A study of Rattus norvegicus with 4 samples.

How the data were processed

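The samples were cultures of olfactory ensheathing cells from male Fischer rats, sorted by flow cytometry into cells with high and low p75. Per the labels, 4 biological replicates were taken, each with a p75High and a p75Low sample of 98% purity, and the samples were paired. Per the labels, mRNA was bound to magnetic beads, copied to cDNA and amplified by a global PCR (SuperAmp), and 250 ng of cDNA went into each labelling. The p75High cDNA carried Cy5 (red) and the p75Low cDNA carried Cy3 (green) on each of the 4 arrays, so the direction of every ratio comes from the labels, and no array had the dyes exchanged. Amplification by PCR and the fixed dye order can both act on the ratios, and neither was undone here.

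Per the file headers, the arrays were of Agilent rat design 014879 and were read with Feature Extraction 10.5.1.1. The submitters' processing notes name Agilent Feature Extraction 10.5. The deposited intensity values, per the file headers, were the mean pixel brightness of each spot and the median brightness of its local background, in each channel and without normalization. The deposited log10 ratios of red over green were made, per the file headers, from background-subtracted, detrended and dye-normalized signals. The authors' value table of the series held the same log10 ratios as the scanner files, with a maximum difference of 0, so its scale and direction were known and it was not a separate alternative. The median of each of its 4 columns was 0. The headers placed the 4 arrays on 1 slide.

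Spot intensities were background-corrected with normexp (offset 50) and normalized by loess (span 0.3) within each array in limma 3.58.1 under R 4.3.3. The 1639 control spots and the spots marked as outliers had weight 0 in the loess fit. Of 173516 readings of the 43379 gene spots, 1112 (0.64%) were marked as outliers and left out, and 0 spots were saturated. Repeat spots of a probe were averaged, which gave 41012 probes. A probe was kept when it was well above background in the same channel on at least 3 of the 4 arrays, which left 24941 probes. The brightest kept probe stood for a gene, which left 22192 genes, 10681 of them with a gene symbol. For genes taken by the rule below, other kept probes are given where they differed from the brightest by over 1 on the log2 scale.

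Probe names were updated through a RefSeq gene table of the GRCr8 assembly, used for names alone. Of the 41012 probes, 10928 matched by accession, 5183 by symbol and 3471 by an older symbol, and 21430 were unmatched and kept the name in the file. Coordinates are those of the array file, and their genome build is not given in the sources used here. Whether a probe lies in an exon or an untranslated region was not analysed here.

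The comparison was the log2 ratio of p75High over p75Low against 0, fitted with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment at 0.05. Both channels of an array belong to 1 replicate, so the ratio is the paired difference, as the labels' design text states. After removal of the group means, the correlation across genes between the channels of the same array was 0.13, 0.06, 0.07 and 0.26 for replicates 1 to 4, and the highest with a channel of another array was 0.05. A gene not well above background in any array of a population would have been given as a bound, and 0 genes past the threshold needed one.

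Of 18 gene lists, 17 held at least 3 tested genes and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 17 lists. The lists covered glia, myelin, fibroblasts, smooth muscle, astrocytes, microglia and macrophages, endothelium, neurons, epithelium, growth factors, matrix, proteases, axon guidance, cell cycle, inflammation, dissociation stress and housekeeping. The remaining list held Ngfr alone. At the preset correlation, camera takes its degrees of freedom from the number of genes, and at an estimated correlation from the number of arrays. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took Ngfr, then the 8 largest and 8 smallest ratios among genes past the threshold with the same sign on all 4 arrays and a gene symbol. It also took up to 3 members of each list past the threshold, by size of ratio, or the 2 with the smallest p where none passed. Symbols were judged after the update, so Spin2a, Kdm5b and Or2d2 entered although the array file gave them predicted names. Some genes that the rule took are not reported here.

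The fit was tested on simulated data with the spread of the 22079 genes that had a reading on all 4 arrays. In the simulated p75High over p75Low comparison, 0 of 50 genes changed 2-fold, 0 of 50 changed 4-fold, 14 of 50 changed 16-fold and 24 of 50 changed 64-fold were recovered, and 2 unchanged genes passed. With 3 arrays, 0 of the 50 genes changed 64-fold were recovered. In a simulation of the list test over the same 22079 genes, a list shifted by 2 on the log2 scale was called and 0 of 16 unshifted lists were. The simulated genes were independent of each other, so this does not check the list test where members vary together. The number of arrays limits the precision of every value.

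The alternatives were no filter on dim probes, a stricter filter, no background correction, the scanner log10 ratios, median centring, outlier spots kept, a median over probes, array weights, both channels as independent samples and each replicate left out. Slide as a block could not be fitted because the arrays shared 1 slide. No column of per-sample values lacked a sample.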

Results

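Olfactory ensheathing cells are glia that wrap the axons of olfactory neurons. Cultures of these cells from male Fischer rats were sorted on p75, the low-affinity neurotrophin receptor, into p75High and p75Low populations. Gene expression was measured on 4 Agilent arrays of 45018 spots, 1 array for each of 4 biological replicates. Each array carried p75High cDNA in Cy5 and p75Low cDNA in Cy3. Between 22464 and 28062 probes per array were well above background in the p75High channel, and between 23044 and 26174 in the p75Low channel. Values are log2 ratios of p75High over p75Low, as mean ± SD (n = 4 arrays), with adjusted p from limma. The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be partly technical.

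The comparison asked which genes differed between ensheathing cells with high and low p75. Ngfr, which encodes p75, was higher in p75High by 5.80 ± 0.53, a 55.9-fold ratio (SE 0.34, adjusted p = 0.0262). Its ratio was positive on all 4 arrays, at 6.07, 6.17, 5.02 and 5.96 for replicates 1 to 4. The value is the mean of 10 repeat spots of 1 probe, placed by the array file on chromosome 10 at 84263082 to 84263141. The direction of the Ngfr ratio matched the sort gates on each array.

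Genes of microglia and macrophages were lower in p75High. Of the 14 tested members of that list, 8 were lower past the threshold and 6 did not pass. Adjusted over the list alone, 11 were lower. On all 4 arrays, 13 of the 14 had a negative ratio, and the list median was -4.57 (camera adjusted p = 9.38e-17, fry adjusted p = 0.00172). With an estimated correlation, the camera adjusted p was 0.125. Ctss, a lysosomal protease of antigen-presenting cells, was lower by -6.11 ± 0.79 (adjusted p = 0.0262). Itgam, an integrin subunit of myeloid cells, was lower by -5.77 ± 0.33 (adjusted p = 0.0262), with its probe placed on chromosome 1 at 187385032 to 187385565. Csf1r, the receptor that macrophages need for survival, was lower by -6.08 ± 0.61 (adjusted p = 0.0262) by its brightest probe. Its other probes read -0.25 and 0.41, and the median over its probes ended the call (-0.25, adjusted p = 0.712).

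The remaining genes with a gene symbol and the smallest ratios included further genes of immune cells. Anxa3, an annexin, was lower by -6.24 ± 0.51, a 75.7-fold ratio. Naaa, a lysosomal hydrolase of fatty acid amides, was lower by -6.18 ± 0.66. Fcgr2a, a receptor for the Fc part of IgG that the array file named Fcgr3, was lower by -6.16 ± 0.56. Cxcl13, a chemokine for B cells, was lower by -6.02 ± 0.93, and Slfn2, of the schlafen family, by -5.97 ± 0.96. Adgre1, a macrophage surface receptor, was lower by -5.87 ± 0.69. The adjusted p of these genes was 0.0262. The other probes of Anxa3 read -4.82 and -1.63, and those of Fcgr2a read -2.99 and -5.59. The median over its probes ended the call of Anxa3 (-4.82, adjusted p = 0.201), and without the filter on dim probes Cxcl13 (adjusted p = 0.0517) and Slfn2 (adjusted p = 0.0549) did not pass.

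Higher genes with a gene symbol included Tnc, which encodes the matrix glycoprotein tenascin-C. Its ratio was 7.54 ± 0.38, or 185.9-fold. Spin2a, of the spindlin family, was higher by 6.89 ± 1.05 and Fermt2, an activator of integrins, by 6.75 ± 0.59. Serpine2, an inhibitor of serine proteases, was higher by 6.65 ± 1.08, and its other probe read 4.56. Kdm5b, a histone demethylase, was higher by 6.43 ± 0.55. Serpinh1, a chaperone of collagen, was higher by 6.41 ± 0.96. Prnp, the prion protein gene, was higher by 6.34 ± 0.94. Prnp, and the brightest probe of Kdm5b, were well above background in the p75Low channel on 2 of the 4 arrays, while Kdm5b was so on all 4 arrays over its 3 probes. With the scanner ratios, Kdm5b (9.07) and Prnp (9.02) exceeded Tnc (7.83). Or2d2, an olfactory receptor gene, was higher by 6.28 ± 0.95. The adjusted p of these 8 genes was 0.0262. The other probes of Kdm5b read 4.17 and -0.73, and the median over its probes ended its call (3.82, adjusted p = 0.316). Spin2a did not pass with median centring (adjusted p = 0.053), and Serpine2 did not pass without the filter (adjusted p = 0.0549).

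**Figure D1:**
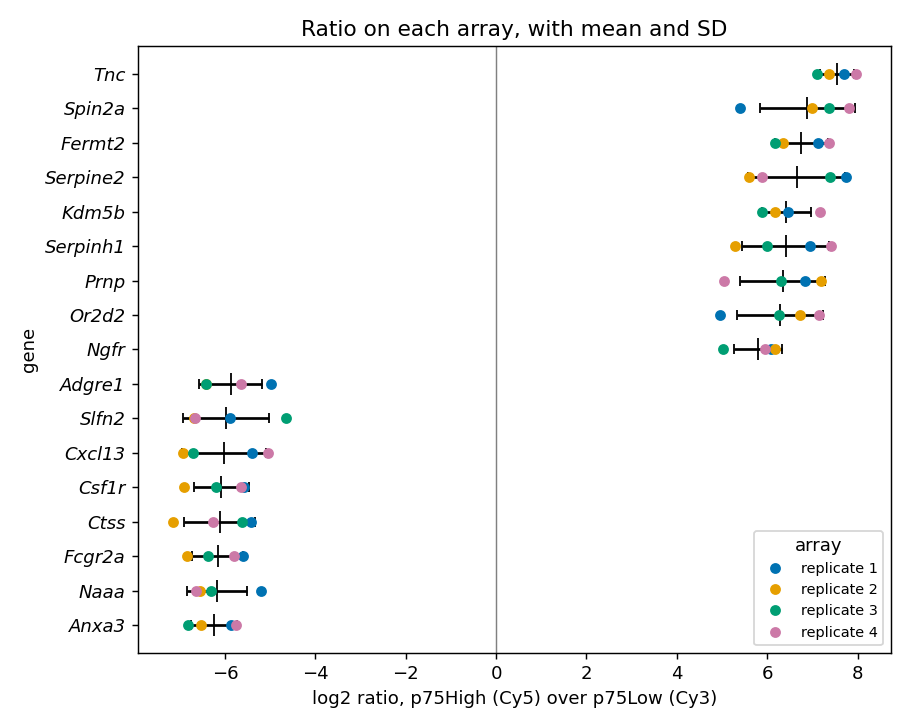
Log2 ratio of p75High (Cy5) over p75Low (Cy3) on the horizontal axis for Ngfr and the largest and smallest ratios among genes past the threshold with a gene symbol and the same sign on all 4 arrays. Coloured points are the 4 arrays, the black tick is the mean and the bar is 1 SD, and Tnc lies highest at 7.54 and Anxa3 lowest at -6.24.

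Across the 22192 genes tested, 69 were higher and 97 were lower in p75High. The absolute log2 ratio of these 166 genes ran from 2.53 to 7.54 with a median of 4.96, and 164 of them had the same sign on all 4 arrays. At an unadjusted p under 0.05, 1292 genes were higher and 1533 were lower. The arrays differed widely, with a median SD per gene of 1.14 on the log2 scale and correlations between arrays of 0.17 to 0.25 across genes, which are not independent replicates. The counts fell to 0 in limma without any 1 of replicates 1, 2, 3 and 4 (1884 to 2375 genes at an unadjusted p under 0.05), and Ngfr then had an adjusted p of 0.0963 to 0.138. Counts were 37 higher and 52 lower without the filter on dim probes, 111 and 154 with the scanner ratios, and 152 and 156 with no replicate block, that is, with the pairing ignored.

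Genes of the extracellular matrix and basement membrane were higher in p75High as a list, but unevenly over the arrays. Of 25 tested members, Tnc and Sparc were higher past the threshold, 0 were lower and 23 did not pass. Adjusted over the list alone, 7 were higher and 1 was lower. The list median was 1.16 (camera adjusted p = 0.00221, fry adjusted p = 0.00318), and with an estimated correlation the camera adjusted p was 0.228. Without replicate 1 the median was 0.54 (camera adjusted p = 0.0164). By array, the list median was 1.975, 0.208, 1.27 and 0.043 for replicates 1 to 4. On all 4 arrays, 8 members were higher and 3 were lower. Sparc, a collagen-binding matrix protein, was higher by 4.03 ± 0.82 (adjusted p = 0.0465). It did not pass without the filter (adjusted p = 0.0875), with the scanner ratios (adjusted p = 0.0658) or with median centring (adjusted p = 0.0755).

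Members of the list of extracellular proteases and their inhibitors differed in both directions. Of 17 tested members, 2 were higher, 2 were lower and 13 did not pass. Adjusted over the list alone, 4 were higher and 2 were lower. The list median was 0.66 (camera adjusted p = 0.041, fry adjusted p = 0.0234), and with an estimated correlation the camera adjusted p was 0.343. The higher members included Serpine2, at 6.65 ± 1.08 (adjusted p = 0.0262). The lower members were Cst3, a cysteine protease inhibitor at -4.54 ± 0.89 (adjusted p = 0.0394), and Timp2, a metalloproteinase inhibitor at -4.28 ± 0.90 (adjusted p = 0.0465). Cst3 did not pass without the filter (adjusted p = 0.0783). Timp2 did not pass without the filter (adjusted p = 0.0876), with the scanner ratios (adjusted p = 0.0575), with median centring (adjusted p = 0.0918) or with the pairing ignored (adjusted p = 0.0511). The list itself did not pass without replicate 2 (median 0.84, adjusted p = 0.155) or without replicate 3 (median 1.63, adjusted p = 0.0533), nor in 5 of the other settings. Its median was 1.29 with the stricter filter.

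The list of ensheathing and Schwann lineage glia did not pass (median 0.37, camera adjusted p = 0.167). Its median was 0.16 without replicate 3, 0.58 to 0.61 without replicate 1, 2 or 4, 0.56 with no background correction and 1.22 with the scanner ratios, and it passed in none of these. Of its 20 tested members, 0 were higher, 1 was lower and 19 did not pass, and adjusted over the list alone 1 was higher and 1 was lower. The lower member was Apoe, a lipid carrier made by glia and macrophages, at -5.11 ± 0.89 (adjusted p = 0.0313). Apoe did not pass without the filter on dim probes (adjusted p = 0.061). Sox10, the transcription factor of the neural crest glia, had a ratio of 4.56 ± 1.90 (adjusted p = 0.155), and S100b had 3.75 ± 2.42 (adjusted p = 0.3). Both are values outside the rule for named genes and were chosen after they were seen. Myelin genes gave 0 of 8 past the threshold (median 0.25, camera adjusted p = 0.624), and their median ran from -0.10 without replicate 3 to 0.51 with the scanner ratios. In that list Mag read 0.86 ± 0.85, and 0.45 without replicate 4.

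Lists of other cell types that the cultures could hold did not pass. Of 17 fibroblast genes, 0 passed over all genes and 4 higher and 1 lower passed adjusted over the list alone (median 0.41, camera adjusted p = 0.167). The fibroblast median was 1.31 with the scanner ratios, 0.63 with no background correction, -0.01 with no filter or the stricter filter, and 0.27 and 0.23 without replicates 1 and 2. Col5a2 read 6.17 ± 1.75 (adjusted p = 0.0639) and Postn 4.80 ± 1.60 (adjusted p = 0.097). Of 13 smooth muscle and pericyte genes, 0 passed over all genes and 3 higher and 1 lower passed adjusted over the list alone (median 0.17, camera adjusted p = 0.257). Their median was -0.04 without replicate 3, 0.52 without replicate 4, 0.36 with the scanner ratios, 0.35 with median centring and 0.30 with no background correction. Mcam read 5.15 ± 2.27, with 2.48 by its other probe, and Tpm1 read 3.08 ± 1.72, with 0.66, 1.61 and 3.20 by its other probes. Of 9 astrocyte genes, 0 passed over all genes and 1 lower passed adjusted over the list alone (camera adjusted p = 0.815). The astrocyte median was -0.05, with -0.15 to 0.20 over the settings, and its mean 0.00. Glul, which makes glutamine, read -2.37 ± 0.37 (adjusted p = 0.0678), with -4.20 by its other probe, and Aldoc read 2.16 ± 2.35, with 1.00 without replicate 1 and 3.31 with the scanner ratios. With the pairing ignored, Col5a2 (adjusted p = 0.015), Postn (adjusted p = 0.0185), Mcam (adjusted p = 0.0225) and Glul (adjusted p = 0.0144) passed. Col5a2 also passed with the stricter filter (adjusted p = 0.0459) and with the scanner ratios (adjusted p = 0.0491). In the endothelial (8 tested, median 0.58, camera adjusted p = 0.0966), neuron (8 tested, median -0.18, camera adjusted p = 0.955) and epithelial lists (7 tested, median 0.24, camera adjusted p = 0.167), 0 genes passed, over all genes or adjusted over the list alone. Cldn5 read 1.23 ± 0.80, Vwf 1.15 ± 0.77, Rbfox3 -0.86 ± 0.37, Syt1 0.68 ± 0.16, Krt14 1.57 ± 0.63 and Krt8 0.89 ± 0.94. The other probe of Vwf read 0.08 and that of Krt14 read 0.39. With the scanner ratios Vwf read 1.83, Rbfox3 -1.65, Syt1 1.73 and Krt8 2.13, and Krt8 read 0.49 without replicate 1. The endothelial list passed with outlier spots kept (median 0.70, adjusted p = 0.0375), and its median was 0.95 with the scanner ratios, 0.29 with the stricter filter, 0.38 with no filter and 0.94 without replicate 3. Over the settings the neuron median ran from -0.33 without replicate 3 to 0.12 without replicate 2, and the epithelial median from 0.13 with no filter to 0.61 without replicate 2.

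**Figure D2:**
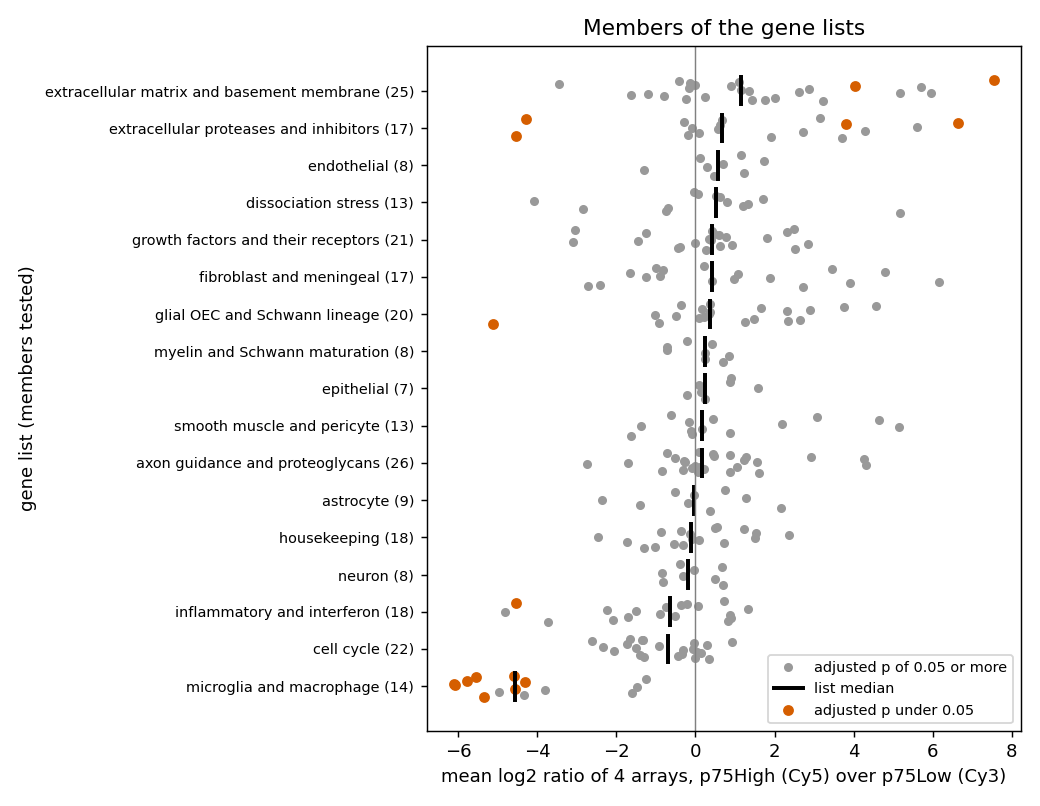
Mean log2 ratio of p75High (Cy5) over p75Low (Cy3) over the 4 arrays on the horizontal axis for each tested member of the 17 lists, 1 list per line. Orange points have an adjusted p under 0.05, grey points do not, and black bars are list medians, of which that of microglia and macrophages lies lowest at -4.57.

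Growth factor genes gave 0 of 21 past the threshold (median 0.42, camera adjusted p = 0.083), with Vegfa at a 5.7-fold ratio (SD 0.93 on the log2 scale) and Gfra1, a receptor subunit for a neurotrophic factor, at 2.85 ± 1.40. The other probe of Vegfa read -0.15, which gave 1.18 as the median over its probes, and that of Gfra1 read 0.97. Axon guidance and proteoglycan genes gave 0 of 26 (median 0.17, camera adjusted p = 0.224), with Sdc3 at 4.27 ± 1.73 and Ncan at 4.32 ± 2.79. Cell cycle genes gave 0 of 22 (median -0.68, camera adjusted p = 0.0966), with Prc1 at -2.60 ± 1.18 and Kif11 at -2.07 ± 1.48. With the scanner ratios they read -4.86 and -4.84. Their brightest probes were well above background in the p75High channel on 2 and 1 of the 4 arrays. The cell cycle median was -0.29 without replicate 2, and the growth factor median was 0.21 without replicate 4. The growth factor list passed with the stricter filter (median 0.45, adjusted p = 0.0423). The axon guidance median ran from 0.09 without replicate 2 or 4 to 0.54 with the scanner ratios. Adjusted over the list alone, none of these 3 lists had a member past the threshold. Of 18 inflammatory and interferon genes, 1 was lower over all genes and 2 adjusted over the list alone (median -0.64, camera adjusted p = 0.136, and median -0.31 without replicate 2 and -0.11 with no filter). Dissociation stress genes gave 0 of 13 over all genes and 3 higher and 1 lower adjusted over the list alone (median 0.51, camera adjusted p = 0.369, and median -0.33 without replicate 1 and 0.02 with no filter), with Atf3 at 5.18 ± 1.38 (adjusted p = 0.0588) and Ier3 at -4.09 ± 2.29. Atf3 passed with the stricter filter (adjusted p = 0.0429), no background correction (adjusted p = 0.0485), the scanner ratios (adjusted p = 0.046) and the pairing ignored (adjusted p = 0.0176). Housekeeping genes gave 0 of 18 over all genes and adjusted over the list alone (median -0.11, with -0.29 to 0.19 over the settings, camera adjusted p = 0.842), with Actb at -1.30 ± 0.73 and B2m at -1.02 ± 0.53. The other probes of B2m read -1.04, -1.29 and -3.35.

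Because p75High carried Cy5 on every array, a dye effect on a single gene cannot be separated from a difference between the populations. The slopes of observed against expected ratios of the spike-in controls, as the scanner software gave them, were 0.166, 0.135, 0.121 and 0.066 on the 4 arrays, with correlations of 0.005 to 0.211, so these controls did not check the ratio scale.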

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

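The tests of spot noise, of lost fragments, of brightness and GC content, of the second myeloid list and of other probes were set before their results were seen. The tests of a lower share of the p75High cells and of a differing cell mix were chosen afterwards.

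A single array stood apart from the other 3 in 4 of 64 sets of array values, where chance gives about 1 in 20. Cldn5 read 2.43 in replicate 1 and 0.80 to 0.87 in the others. The median of the growth factor list was 0.64 in replicate 4 and 0.24 to 0.30 in the others. The axon guidance median was -0.07 in replicate 3 and 0.11 to 0.15 in the others. The dissociation stress median was 1.30 in replicate 1 and -0.40 to -0.22 in the others. Among control spots outside the comparison, 5 of 10 E1A spike-in sequences were above background in both channels on all 4 arrays, against 0.49% of negative control readings.

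The lower microglia and macrophage genes (median -4.57) were weighed first. The lowest median among 10000 random lists matched on probe brightness and GC content was -2.20, which argues against a dye bias that follows GC content. For brightness the test cannot decide, since the loess fit had already removed a trend with brightness on each array. A dye bias of single genes stays open, since no array had the dyes exchanged. The gap between the myeloid median and the nearest of 5 other cell type medians was 4.39. It was set against a lower share of p75High cells that raised every other cell type alike. These medians were known when the test was chosen, and genes of cell types scarce in both populations could show little difference whatever the share. The test therefore cannot decide on that explanation. Myeloid cells in the p75Low gate remain a candidate source: a second myeloid list of 60 genes, none on a fixed list, had a median of -2.15 over 46 tested genes, with Mpeg1 at -4.81, Ctsb at -3.81, Cd63 at -0.99 and Ctsd at -0.22, but 54.3% of its members were lower on all 4 arrays, short of the 60% set beforehand (13% of all genes), and the p75 gate itself would not remove such cells.

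The wide spread between the arrays was weighed second. The 2 brightest probes of a gene deviated together only weakly across arrays (r = 0.19 over 1828 genes, with 0.002 for random pairs). Loss of single fragments in amplification could give this. The mean ratios of these probe pairs correlated at 0.47, so pairs that read different transcripts could give it as well. A cell mix that differed between replicates cannot be told apart from the rest: 0 of 8 cell type lists deviated together beyond the upper bound of random lists of its size, but for 4 of the 8 that bound lay above the 0.19 of 2 probes of the same gene, so such lists could hardly pass. Spot and scanning noise was not excluded by the test set beforehand, as the SD of repeat spots was 0.10 of the SD between arrays, at the bound of 0.1. Over 178 repeated probes the median SD was 0.093 between repeat spots and 0.92 between arrays. These values argue against noise between spots as the main source of the spread for these probes. No biological explanation other than cell mix was tested.

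Genes past the threshold were read by their brightest probe, and 28 of 33 other kept probes (84.8%) had the same sign, against bounds of 60% and 85% set beforehand. For higher genes 9 of 12 and for lower genes 19 of 21 did. Turned to the side of the call, the median of these other probes was 2.10, against 5.14 for the brightest probes, and some of the same sign lay near 0, such as that of Amotl2 (0.05). The genes were called by the ratio of their brightest probe, so smaller ratios of other probes can arise from that selection alone. A probe that reads another sequence stays possible for single genes such as Kdm5b and Csf1r.

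The real signs of the 4 arrays gave 166 genes past the threshold, and the highest count among the other sign patterns was 0. Only 1 of the 8 patterns gave as many genes, and 8 patterns are too few for a share under 0.05.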

How the results depend on the processing

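All alternatives were set before the data were examined. Each of the 166 genes past the threshold kept its sign in every setting. For the 164 with the same sign on all 4 arrays, leaving out a replicate could not have turned it. Counts of higher and lower genes were 37 and 52 with no filter on dim probes and 111 and 154 with the scanner ratios. With no replicate block (the pairing ignored) they were 152 and 156. More genes were tested without the filter. With the pairing ignored, both channels of each array counted as samples, which raised the residual degrees of freedom. How far this accounts for the counts, and the cause with the scanner ratios, was not tested. Counts were 0 and 0 without each replicate, and Ngfr then ranged from 5.68 to 6.07 and did not pass. The simulation with 3 arrays also recovered 0 genes, so fewer arrays alone can give such counts. Few of its 22079 genes were changed, so it does not settle the cause here. The microglia (-4.57) and matrix (1.16) lists lost their calls with an estimated correlation, as did the protease list (0.66). The estimates were 0.077, -0.031 and -0.045. For the matrix and protease lists, a correlation above the preset 0.01 therefore does not account for the lost call. With an estimated correlation, camera takes its degrees of freedom from the 4 arrays instead of the genes, which can lose a call by itself. For the microglia list, the estimate of 0.077 and this change were not separated. The protease list also lost its call with no filter (0.55), no background correction (0.72), the scanner ratios (0.78) and median centring (0.86). The call was lost as well with the probe median (0.66) and without replicates 2 and 3 (0.84 to 1.63). The endothelial list passed with outlier spots kept (0.70) and the growth factor list with the stricter filter (0.45). Median centring moved the median of all genes from -0.03 to 0.13. List medians that turned sign, none of them past the threshold, were myelin without replicate 3 (-0.10, up to 0.49 without another), fibroblast with no filter (-0.01) and the stricter filter (-0.01), smooth muscle without replicate 3 (-0.04, up to 0.52), astrocyte with no filter (0.00), the stricter filter (0.16), median centring (0.12) and without replicate 3 (0.20, down to -0.15), neuron with median centring (0.01) and without replicate 2 (0.12, down to -0.33), dissociation stress without replicate 1 (-0.33, up to 0.73), and housekeeping with median centring (0.19) and without replicates 1 and 4 (0.05 and 0.12, down to -0.11); the cause was not tested. Ignoring the pairing changed no list call. Of 46 named genes other than Ngfr, 0 turned sign in any setting, which leaving out a replicate could not do where all 4 arrays had the same sign. Slide was not run as a block, since the arrays shared 1 slide. Signal over background limits dim genes.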

Other observations

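The genes and classes in this part were chosen after their values were seen, except the lymphoid list, which was set before its values were seen.

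Further genes were higher in p75High. Igfbp5, which binds insulin-like growth factors, read 5.88 (adjusted p = 0.0392). Notch3, a receptor of the Notch pathway, read 3.63 (adjusted p = 0.0262), with 3.39 to 3.96 on the 4 arrays. Plk2 read 5.51 (adjusted p = 0.0334), Rgs16, a regulator of G protein signals, 5.67 (adjusted p = 0.0392), Dnm3 6.11 (adjusted p = 0.0301) and Amotl2 4.53 (adjusted p = 0.0281), with 0.05 by the other probe of Amotl2. Aqp2, a water channel of kidney collecting ducts, read 6.22, and Cela2a, a pancreatic elastase, read 5.92 (both adjusted p = 0.0262). Both were lowest in replicate 1 (5.3 and 4.74) and highest in replicate 4 (7.14 and 6.84), as were the 3 olfactory receptor genes below. Neither Aqp2 nor Cela2a had another kept probe, so a probe that reads another sequence stays possible for them. Among further lower genes, Cd4 read -5.71, Mrc1, a mannose receptor of macrophages, -4.65 and the cytokine Il18 -5.27 (all adjusted p = 0.0262).

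Cathepsins gave 3 lower genes of 16 tested, Ctss (-6.11), Ctsz (-5.32) and Ctsb (-3.81), or 18.75% against 0.46% of other named genes. A shift of the whole family was tested on the 13 members that did not pass. Their median was -0.35, and 12.6% of 1000 matched random lists lay as low, so the values decide neither way.

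Olfactory receptor genes gave 3 higher genes of 493 tested, Or2d2 (6.28), Or2av9 (5.08) and Or52z1 (4.94), or 0.61% against 0.35% of other named genes. The median of the 490 others was 0.10 against 0.00 for matched random lists, and 0.0% of 1000 such lists lay as high. The uncalled members thus lay slightly higher as a set. The random lists drew genes singly and do not allow for members that vary together, so whether the class shifted stays undecided. The class median exceeded that of all genes in each setting, by the least with no filter (0.02 against 0.00). A shift of this size is far below the ratios of the 3 genes.

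Lymphoid cells in the p75Low gate were set against a lymphoid list. Of its 18 genes on the array, 11 were tested, with a median of 0.09, which argues against lymphoid cells as the source of the lower microglia and macrophage genes as a set. Cd4, a T cell gene that rat macrophages also express, was not on the list and read -5.71.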
